A study of Rattus norvegicus with 6 samples.

How the data were processed

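The arrays measured RNA from retinal ganglion cells, the neurons whose axons form the optic nerve, of 3 adult male Brown Norway rats. Per the labels' protocols, the cells were marked by Fluorogold carried back from the superior colliculus, pressure was raised in 1 eye of each rat for 10 days by hypertonic saline in an episcleral vein, and 2000 cells per eye were collected by laser capture. RNA was then isolated with a PicoPure kit, amplified linearly with a RiboAmp HS kit, and 10 µg was labelled with biotin for a 1-colour Affymetrix GeneChip, per the labels' protocols. Each eye gave 1 array. Arrays were processed with GCOS, per the submitters' processing notes; its version and settings are not given in the sources used here.

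The deposited values are intensity values on a linear scale, 1 per probe set, with no detection calls. The mean after trimming 2% from each end was 500.1 on each of the 6 arrays, so the values were taken as globally scaled to a common target before they were deposited. No further normalization between arrays was applied, and the scaling leaves open whether total RNA differed between eyes. The table held 31099 probe sets, of which 57 were Affymetrix controls and stayed out of the tests. Of the other 31042, the platform annotation gave 1 gene symbol for 20826, several for 436 and none for 9780. Gene identifiers of 20764 were found in the reference gene table, and 0 symbols changed. Only probe sets with 1 symbol were named by gene.

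The labels give a rat number and an eye, OD for the right and OS for the left, and do not say which eye had the raised pressure. Arrays were therefore grouped by eye, differences were taken as OS minus OD within each rat, and no array was called treated or control. A difference between eyes here has no known direction with respect to pressure, and if the treated side varied between rats, effects of pressure would partly cancel. Both eyes of a rat share a number because they come from the same animal, as the titles and the design text give it. Deviations from the group means correlated between the 2 eyes across probe sets at 0.109 for rat 1, 0.122 for rat 2 and 0.326 for rat 3 (Pearson's r over probe sets, which are not independent replicates). Between eyes of rats 1 and 2 they correlated at 0.104 and 0.088, about as high, so these values set rat 3 apart but do not show the pairing in rats 1 and 2, which rests on the labels.

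An offset of 16 was added to each value before log2, so fold changes of dim probe sets are understated. Probe sets at or above the median of mean log2 values over the 6 arrays were tested, which left 15521 probe sets for 8594 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with rat as a fixed block, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single probe sets are from this limma fit. Each difference is given with the SD of the 3 within-rat differences. The limma p-values do not rest on this SD alone. The fit had 2 residual and 19.4 prior degrees of freedom, so they rest mostly on variance pooled over probe sets. Gene lists, 25 in number, were fixed before the data were examined; 24 had at least 5 genes tested, and the crystallin list did not. Each gene was represented by its brightest probe set. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with Benjamini-Hochberg adjustment, and each median was set beside the 95% range of 10000 random lists matched on brightness. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with the other genes, while fry tests a list against no change, so the 2 ask different questions.

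Named genes followed a rule fixed before the data were examined. Candidates had 1 gene symbol, the same direction in all 3 rats and a mean difference of at least 2-fold. They were ranked by the unadjusted p of the limma fit, and the 12 best ranked in each direction were named. Added to these were up to 4 members of each tested list with the smallest p, and the ganglion cell markers Thy1, Pou4f1, Sncg, Nefl and Rbpms whatever their values. The 95th percentile of 27 probe sets for bacterial RNAs that are not spiked in served as each array's limit of signal over background. A fold against an eye whose 3 arrays all lay at or below this limit is given as a lower bound, computed against the limit.

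The limma fit was tested on simulated data, with means and variances of the 15521 probe sets and 200 probe sets changed, 50 at each size. It recovered 2% of 2-fold, 10% of 4-fold, 36% of 8-fold and 76% of 16-fold changes for OS against OD, with 1 unchanged probe set called. In unchanged simulated data 0 lists were called. Noise was drawn independently for each probe set, so this does not show the error rate of the list test for correlated genes. In the data, estimated correlations within lists ran from -0.108 for immediate early genes to 0.303 for ribosomal proteins, with 0.202 for amacrine markers. With 1 list of 16 genes lowered by 1.0 on the log2 scale, camera at the preset correlation called that list and 1 other. The other list had not been changed, so it was a false call. The adjusted p of the lowered list was 0.794 with an estimated correlation and 0.202 by fry. Alternatives covered the offset, quantile normalization, the filter on dim probe sets, the block, the prior variance, each rat left out, and the list test. The number of arrays limits the precision.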

Results

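Gene expression was measured in laser-captured retinal ganglion cells from both eyes of 3 rats with raised pressure in 1 eye, a model of glaucoma. The question behind the design was how raised pressure changes expression in these cells relative to the fellow eye. The labels give the eye of each array (OD, right, n = 3; OS, left, n = 3) but not which eye had raised pressure, so the values below compare left with right within rats and carry no direction with respect to pressure.

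The median array value lay between 313 and 370, and the background limit from unspiked bacterial controls lay between 261 and 591. The share of probe sets above this limit was 58.1% in OD and 47.6% in OS of rat 1, 34.8% and 34.9% in rat 2, and 52.1% and 45.5% in rat 3. Of the 15521 tested probe sets, 22.6% exceeded the limit on all 6 arrays. Arrays of the same rat correlated at a mean r of 0.443 across tested probe sets, against 0.344 for the same eye of different rats and 0.320 for different eyes of different rats; probe sets are not independent replicates. The OD array of rat 1 correlated at 0.469 with the OS array of its own rat and at 0.490 with that of rat 2. With the OD array of rat 3 it correlated at 0.503, the highest of all pairs. The first principal component held 34.4% of the variance and set both arrays of rat 3 apart from those of rats 1 and 2.

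**Figure D1:**
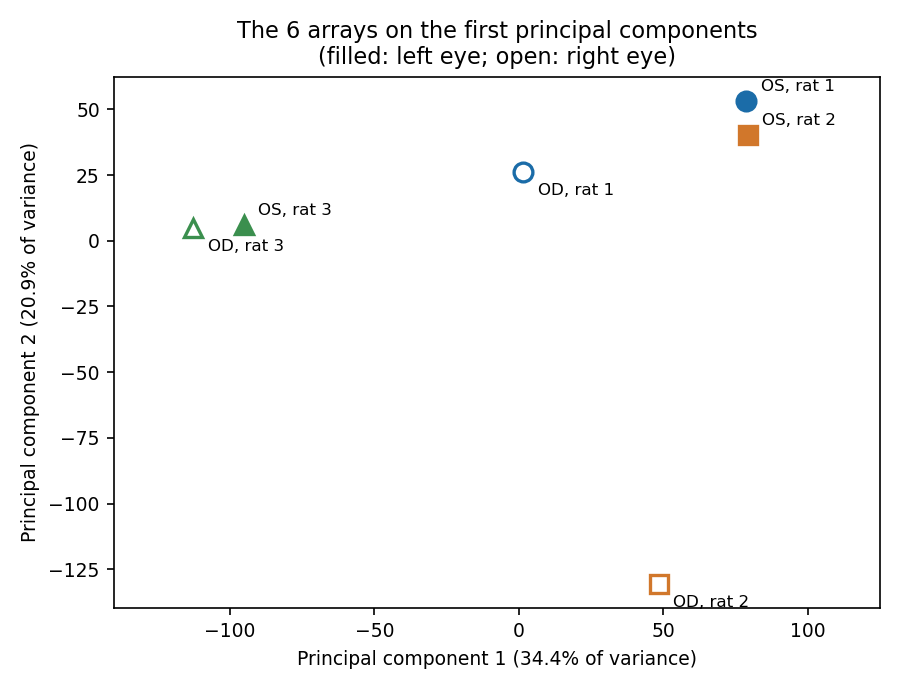
The 6 arrays on principal components 1 and 2 of the tested log2 values, in arbitrary units, with the share of variance on each axis; colour and shape mark the rat, filled points OS and open points OD. Both arrays of rat 3 lie at the left, and the OD array of rat 2 lies alone at the bottom.

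Cpe (1386921_at) encodes carboxypeptidase E, an enzyme that processes neuropeptide precursors. It was lower in OS than in OD in 3 of 3 rats, by a log2 difference of -3.61 ± 2.06 (SD, n = 3 rats, limma adjusted p = 0.0464). Its OS value in rat 2 was 19.8, below that array's background limit of 547, so the size of its difference is uncertain. The unnamed probe set 1374286_at was lower in OS by -4.20 ± 0.31 in 3 of 3 rats at the same adjusted p of 0.0464; its OS arrays all lay below the background limit, so OD was at least 6.31-fold higher. These 2 were the only probe sets past the threshold in the limma fit, and 0 were higher in OS. At an unadjusted p under 0.05 there were 1072 probe sets, 669 lower and 403 higher in OS, where 776 are nominally expected with no difference. Other splits of the arrays into 3 and 3 gave 418 to 709 where they parted every rat. Splits that parted the eyes of only 1 rat gave 639 to 1331. The number 776 is thus not a firm baseline. The count of 2 became 0 without the replicate block (546 at an unadjusted p under 0.05), 0 after quantile normalization and 9 with an offset of 64. It was 26 without rat 1, 59 without rat 2 and 18 without rat 3.

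The other best-ranked genes lower in OS were lower in 3 of 3 rats but missed the threshold. Zwint, a kinetochore protein gene, differed by -2.47 ± 0.47 (adjusted p = 0.113), Ddx5, an RNA helicase gene, by -2.81 ± 0.50 (adjusted p = 0.113), and Tppp, which encodes a tubulin-binding protein, by -2.85 ± 1.44 (adjusted p = 0.113). Pcp4, a calmodulin regulator gene, differed by -2.18 ± 1.28 and the potassium channel gene Kcnc1 by -2.06 ± 0.77. Lcmt1 (-2.11 ± 0.67), Phf14 (-2.81 ± 1.94), Ncoa7 (-2.43 ± 0.61), Prrt1 (-2.51 ± 0.53), Enpp5 (-1.91 ± 0.65) and Pcnp (-2.51 ± 0.75) completed these 12 genes. All 12 were brighter than the background limit on the 3 OD arrays. Ddx5 and Prrt1 exceeded it on 1 of 3 OS arrays, and Cpe, Zwint, Tppp, Phf14, Ncoa7 and Pcnp on 2 of 3. The sizes of these differences are therefore uncertain.

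Of the genes ranked best in the other direction, none passed the threshold, and their smallest adjusted p was 0.282, for the metallothionein gene Mt2A, at 2.09 ± 1.29. Ptgs2, which encodes the inducible cyclooxygenase, was higher in OS by 2.49 ± 1.37, Car3, a carbonic anhydrase gene, by 2.32 ± 1.92, and Itgb6, an integrin subunit gene, by 2.11 ± 0.77. Prtg had the smallest spread, 1.46 ± 0.07. The remaining differences were 2.27 ± 0.50 for Luc7l (1 of its 3 probe sets went the other way), 2.19 ± 1.27 for Ap3s1, 2.99 ± 0.98 for Csgalnact2, 2.64 ± 1.32 for Lacc1, 2.60 ± 1.34 for Crxos1, 2.44 ± 1.37 for Sfr1 and 2.46 ± 1.40 for Rras. Only 1 of 3 OD arrays exceeded the background limit for Ptgs2, Csgalnact2, Lacc1, Crxos1 and Rras, so the sizes of these differences are uncertain.

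Markers of retinal ganglion cells were lower in OS as a list: 14 of the 15 tested genes had a lower mean in OS, 9 of them in all 3 rats, with a median log2 difference of -0.64 (camera adjusted p = 0.00107; adjusted p = 0.563 with an estimated correlation). The neurofilament genes Nefh (-1.72 ± 0.22) and Nefm (-1.41 ± 0.43), whose products build the axonal cytoskeleton, and the RNA-binding protein gene Rbpms2 (-1.75 ± 0.73) were lower in 3 of 3 rats. So were the transcription factor gene Pou4f1 (-2.33 ± 1.04), the surface glycoprotein gene Thy1 (-0.78 ± 0.16) and Rbpms (-0.38 ± 0.18). Pou4f1 exceeded the background limit on only 1 of 3 OS arrays, so the size of its difference is uncertain. Sncg (-0.64 ± 1.70) and Nefl (-0.42 ± 2.67) went different ways in different rats, and both changed sign without rat 1, to 0.34 and 0.13. By limma, 0 genes of the list passed over all probe sets, and 2 passed when adjusted over the list alone.

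**Figure D2:**
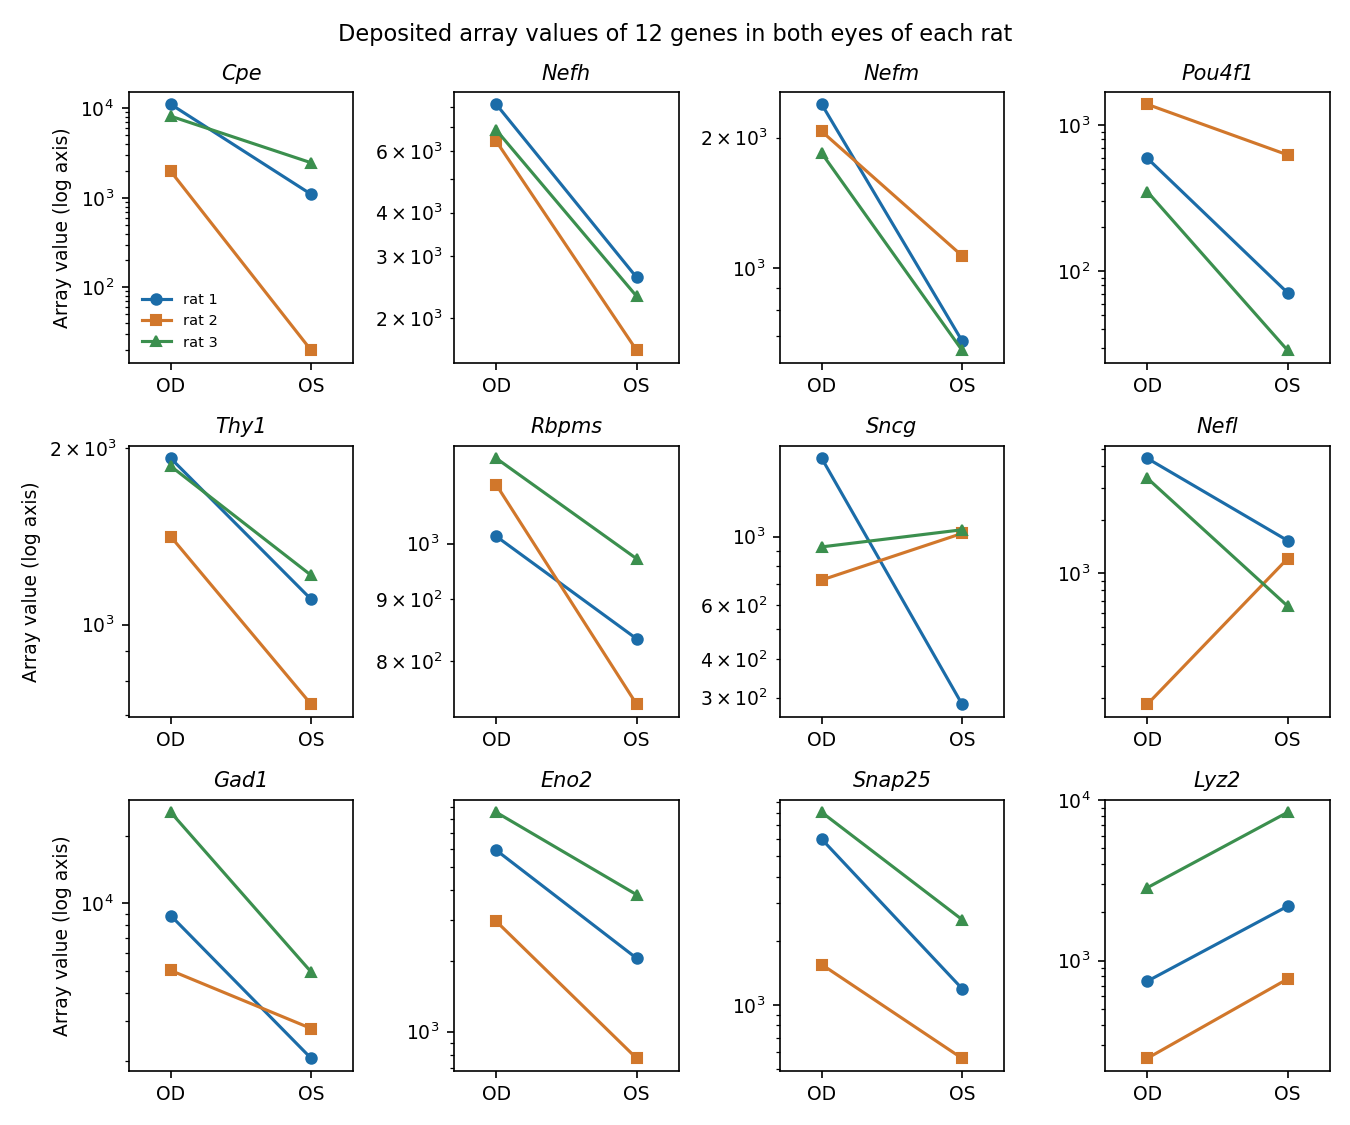
Deposited array values on log axes for 12 genes, with a line joining the right (OD) and left (OS) eye of each rat. Nefh, Nefm, Pou4f1, Thy1 and Rbpms are lower in OS in 3 of 3 rats, Lyz2 is higher in 3 of 3, and Sncg and Nefl go in different directions.

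A further 5 lists were lower in OS, and none of the 6 kept its call with an estimated correlation (camera adjusted p = 0.563 for each). By fry, which tests a list against no change, none of the 6 passed (smallest adjusted p among them 0.370). The amacrine cell marker list had a median of -1.19 over 10 genes (camera adjusted p = 0.0065), with medians of -2.00, 0.33 and -1.95 in rats 1 to 3. Gad1, which encodes a GABA-synthesizing enzyme, differed by -1.77 ± 0.80, Pax6 by -1.57 ± 0.58 and Calb2 by -1.41 ± 0.66. Axonal cytoskeleton and transport genes had a median of -0.59 over 25 genes (camera adjusted p = 0.012). Of these, 19 had a lower and 6 a higher mean in OS, including Tubb2a (-1.68 ± 0.86) and Klc1 (-1.05 ± 0.40, its other probe set higher in OS) but also Kif1a (1.31 ± 2.08). This list shares 5 genes with the ganglion cell list. Glycolysis genes had a median of -0.87 over 17 genes (camera adjusted p = 0.0133), with Eno2 at -1.53 ± 0.38, Aldoc at -1.17 ± 0.37 and Pgam1 at -0.91 ± 0.20. Pigment epithelium and lens markers had a median of -1.03 over 7 genes (camera adjusted p = 0.0185), among them the melanin synthesis genes Dct (-1.95 ± 0.50) and Tyrp1 (-2.57 ± 2.51, its other probe set higher in OS) and the transthyretin gene Ttr (-1.03 ± 0.38). Oxidative phosphorylation genes had a median of -0.50 over 36 genes (camera adjusted p = 0.0365), with medians of -0.79, 0.09 and -0.60 in rats 1 to 3. Of these, 25 genes had a lower and 11 a higher mean in OS, with Ndufa1 at -1.56 ± 1.74 and Cox6a1 at -1.70 ± 1.44. Cox6a1 exceeded the background limit on 1 of 3 OS arrays, so the size of its difference is uncertain. Adjusted over the list alone, 3 amacrine, 2 axonal, 1 glycolysis, 2 pigment epithelium and lens and 0 oxidative phosphorylation genes passed, against 0 over all probe sets.

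Without rat 1, 0 lists passed and the smallest adjusted p was 0.0896. List medians were then -0.52 for ganglion cell markers, -0.60 for axonal, -0.44 for glycolysis, -0.40 for amacrine, -0.17 for pigment epithelium and lens and -0.14 for oxidative phosphorylation genes. Without rat 2 there were 6 and without rat 3 there were 4, and without the replicate block 3 remained below the threshold. The signal of the beta-actin control from the 3' end relative to the 5' end was higher in OS in 3 of 3 rats, by 1.32 ± 0.52 on the log2 scale (exact two-sided sign-flip permutation p = 0.25, the smallest that 3 rats allow), beside these lists. The same difference for the Gapdh control was -0.46 ± 1.86 (exact permutation p = 1), and for the hexokinase control -0.59 ± 3.39 (exact permutation p = 1). Only 1 of the 12 hexokinase values exceeded the background limit, so the hexokinase difference carries little information.

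**Figure D3:**
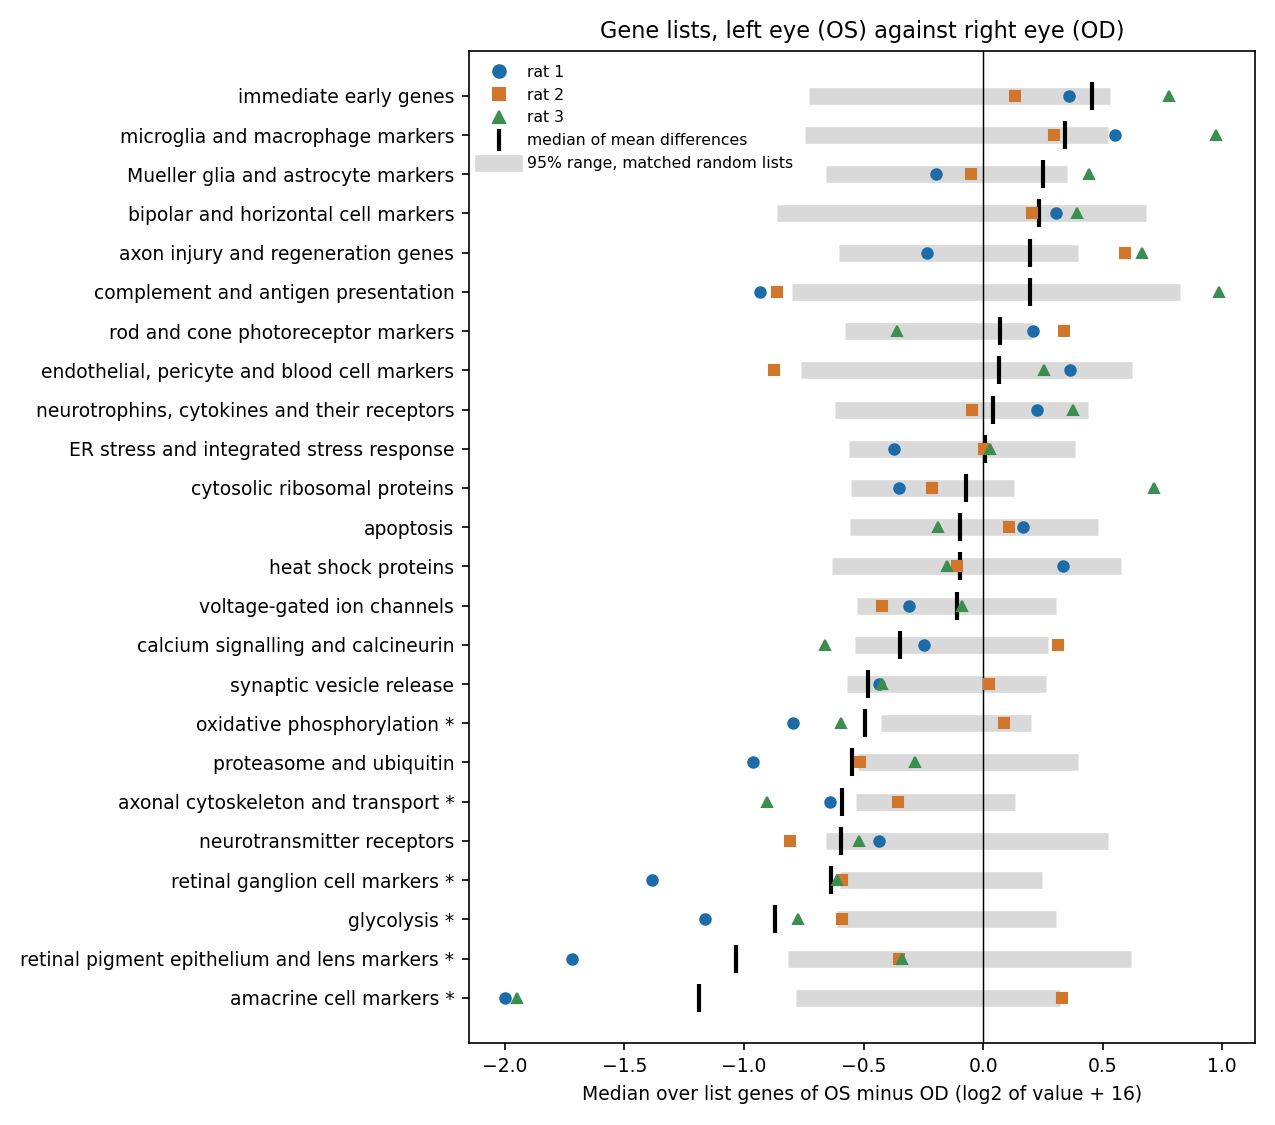
Median OS minus OD difference, in log2 units, of each of the 24 tested lists, per rat (points) and over the mean differences (black ticks), with grey bars for the 95% range of 10000 random lists matched on brightness; asterisks mark the 6 lists with a camera adjusted p under 0.05. The medians of these 6 lie left of their grey bars, and for amacrine cell markers rat 2 lies apart at 0.33.

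The other 18 lists did not pass. Microglia and macrophage markers had a median of 0.34 over 10 genes (camera adjusted p = 0.14). Above the control limit, a filter chosen after seeing the data, this list passed, higher in OS (adjusted p = 0.0414), but there it did not pass with an estimated correlation (adjusted p = 0.458) or by fry (0.107). Within it the lysozyme gene Lyz2 was higher in OS by 1.56 ± 0.02 and the Fc receptor gene Fcgr3a by 1.89 ± 1.27, each in 3 of 3 rats, while Csf1r (0.70 ± 1.47) and Laptm5 (-1.23 ± 1.33) went different ways in different rats. Fcgr3a exceeded the background limit on 1 of 3 OD arrays and Lyz2 on 2 of 3, so the sizes of their differences are uncertain. Neurotransmitter receptors had a median of -0.60 over 13 genes (camera adjusted p = 0.14) and voltage-gated channels -0.11 over 21 (camera adjusted p = 0.147), with Kcna2 at -1.63 ± 0.84. Synaptic vesicle genes had a median of -0.48 over 21 (camera adjusted p = 0.151, and above the control limit 0.0320, lower in OS, but 0.458 with an estimated correlation and 0.305 by fry), with Snap25, a vesicle fusion gene, at -1.81 ± 0.46 and Napa at 1.30 ± 1.24. Immediate early genes had a median of 0.46 over 10 genes (camera adjusted p = 0.147). Photoreceptor markers had a median of 0.07 over 20 genes, with Rom1 at -1.02 ± 0.17 and Gnb1 at 1.47 ± 0.76 (its other probe set lower in OS), and glial markers had 0.25 over 14, with Gfap at 0.86 ± 1.27 and Rlbp1 at -1.51 ± 2.18. In the complement and antigen presentation list, C3, above the limit on 1 of 3 OD arrays, was higher in OS by 2.87 ± 1.31, and C1r, at or below the limit on all 3 OS arrays, was at least 1.59-fold higher in OD. Apoptosis (median -0.09), heat shock (-0.10), ER stress (0.01) and axon injury genes (0.20) lay within the range of matched random lists. Proteasome and ubiquitin genes had a median of -0.55 over 21 genes, below that range, and did not pass by camera (adjusted p = 0.198).

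The left-right differences were little shared between rats. Across tested probe sets, which are not independent replicates, r of the differences was 0.0343 for rats 1 and 2, 0.1002 for rats 1 and 3 and 0.0148 for rats 2 and 3. At least 2-fold apart in each of the 3 rats were 1241 probe sets, of which 408 (32.9%) had the same direction in all 3, 227 lower and 181 higher in OS, where chance gives 25%. The other 833 had mixed directions, with rat 1 opposite to the others in 233, rat 2 in 339 and rat 3 in 261. Among the 1553 brightest probe sets, r was 0.232, 0.271 and 0.147 for the same pairs.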

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

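The tests in this part were chosen after the values were seen. The control probe sets for 5S ribosomal RNA and for the B1 repeat, which no comparison used, gave signal above the background limit on all 6 arrays: the lowest values were 1139.7 for 5S ribosomal RNA and 2796.6 for the B1 repeat. Both were lower in rat 3, where the B1 repeat averaged 3611 over 2 arrays, against 10799 ± 734 (SD, n = 4 arrays of 2 rats) in rats 1 and 2. For 5S ribosomal RNA the averages were 1201 and 3806 ± 1301 (SD over the same 4 arrays). Arrays of 1 rat are not independent, so these SDs do not measure spread between animals. The B2 repeat control was 158.1 on the OD and 670.2 on the OS array of rat 3. In rats 1 and 2 it lay between 498.8 and 731.1, so it did not set both arrays of rat 3 apart. It was below the background limit on the OD arrays of rats 2 and 3 and the OS array of rat 2.

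Rat 3 also stood apart on the first principal component: 224 tested probe sets were at least 4-fold lower on both of its arrays than on the other 4, and 2 were higher, against 23 and 3 for rat 1 and 70 and 1 for rat 2. Of the 224, 192 lay at or below the background limit on both arrays of rat 3. For spike-in brightness and share of probe sets above background, 0 of the 4 values of rat 3 lay outside the range of the other arrays. Those ranges were wide, 64946 to 140137 and 34.8% to 58.1%, and the values had been scaled before they were deposited. A weaker labelled signal on the arrays of rat 3 was therefore not seen but cannot be excluded. A different content of unannotated or repeat-derived RNA in rat 3 may contribute, since 73.2% of the 224 lower probe sets had no gene symbol (exact 95% interval 66.9 to 78.9), against 31.2% of all tested, 32.9% of those lower in rat 2 and 4.35% of those lower in rat 1. That share was 73.2 percentage points above the share among the probe sets higher in rat 3. These numbered only 2 after the brightness filter (exact 95% interval 0 to 84.2), so this explanation cannot be told apart from others. The repeat controls were divided, with B1 lower on both arrays of rat 3 and B2 on its OD array only. The labels give no batch, and differences between individual animals were not tested.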

How the results depend on the processing

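The filter at the control limit and array weights were added after the data were seen; the other alternatives were planned. The count of 2 probe sets past the threshold was 0 with an offset of 1, after quantile normalization, among the probe sets from the 75th percentile of brightness up, above the control limit, without the replicate block, with rat as a random replicate block and without the intensity trend. It was 1 with a robust prior variance, 7 with array weights, 9 with an offset of 64, 9 without a filter, and 18 to 59 with 1 rat left out. The count of 6 lists was 8 above the control limit, where synaptic vesicle genes (lower in OS, adjusted p 0.0320) and microglia markers (higher in OS, adjusted p 0.0414) also passed, but there neither passed with an estimated correlation (0.458 for both) or by fry (0.305 and 0.107), both tried after the data were seen. It was 3 without the replicate block, 3 with a random replicate block, 1 without the trend, 0 with estimated correlations, 0 by fry, and 0 to 6 with 1 rat left out. Adjusted p-values of oxidative phosphorylation were 0.0923 after quantile normalization and 0.117 from the 75th percentile up, where the pigment epithelium and lens list had too few genes to test. Glycolysis, oxidative phosphorylation and pigment epithelium and lens markers had 0.0626 without the replicate block, and 0.0549, 0.0549 and 0.0555 with the random replicate block. Without the trend, each of the 6 lists but ganglion cell markers had 0.0911. With estimated correlations all 6 had 0.563. By fry the values were 0.370 for ganglion cell and axonal genes, 0.427 for glycolysis and pigment epithelium and lens, and 0.510 for amacrine and oxidative phosphorylation. Averaging the probe sets of a gene gave 0.0775 for pigment epithelium and lens. With 1 rat left out, adjusted p ranged from 0.000125 to 0.0896 for ganglion cell markers, 5.63e-06 to 0.111 for amacrine, 0.00313 to 0.111 for axonal, 0.00432 to 0.114 for glycolysis, 0.00432 to 0.111 for pigment epithelium and lens and 0.000413 to 0.509 for oxidative phosphorylation; each highest value was without rat 1. The 408 probe sets at least 2-fold apart in the same direction became 1287 without a filter, 147 from the 75th percentile up, 222 above the control limit, and 1488 to 1642 with 1 rat left out, as more or fewer probe sets were tested or fewer rats had to concur. The mean r of the differences, 0.0498, was 0.104 from the 75th percentile up and 0.0148 to 0.1002 with 1 rat left out. Of 1511 values of 121 named genes, 1455 kept their direction and side of the threshold, 34 newly passed, 8 no longer passed and 14, of 12 genes, changed sign, each with 1 rat left out. The 8 that no longer passed were all values of Cpe, the only named gene past the threshold in the limma fit. The other named genes had no call to lose, so the 1455 says little about how stable calls are. The log2 ranges of the 12 genes that changed sign were -2.82 to 0.15 for Cplx2, -1.20 to 0.34 for Sncg, -1.94 to 0.55 for Nefl, -0.016 to 1.21 for Jund, -0.27 to 2.74 for Egr3, -0.24 to 0.96 for Otx2, -0.74 to 0.81 for Grm6, -2.26 to 0.14 for Hspa5, -2.68 to 0.019 for B2m, -0.34 to 1.46 for Fos, -1.15 to 0.36 for Igf1 and -1.74 to 0.17 for Bag3. Where no reason is given, the cause was not tested. Signal over background limits the dim probe sets: 22.6% of those tested exceeded the limit on all 6 arrays.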

Other observations

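The test of muscle genes was fixed before their values were seen; the tests of scaling, cell share and RNA length were chosen after the list results were known, and the wording of the count of splits was corrected afterwards. All 5 probe sets of Myh1, which encodes a myosin heavy chain of fast skeletal muscle, were among the 40 brightest of the arrays, with the brightest between 47390 and 141094; this gene was chosen after its values were seen. Skeletal muscle RNA in the captured material, a candidate explanation, is argued against: of 17 other muscle genes, 0 had their brightest probe set above the background limit on all 6 arrays, and the geometric mean was 167 for Acta1, 239 for Ckm and 275 for Tnnt3, abundant transcripts of muscle. What the Myh1 probe sets detect stays open.

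Among probe sets at least 4-fold apart between rat 3 and the other rats on every array, the 2 higher in rat 3 were Adamts1, a secreted metalloprotease gene, and Srprb, at or below the background limit on 2 and 4 of the other 4 arrays and at least 6.46-fold and 3.84-fold higher in rat 3. Named ones that were lower included Txlnb, Zfp800 and Bcl11a, at or below the limit on both arrays of rat 3 and there at least 7.26-fold, 6.14-fold and 3.98-fold lower. These were chosen after their values were seen and were not tested.

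All 6 lists that passed were lower in OS. Against brightness-dependent scaling, all 6 had medians below the range of matched random lists, and 5 of the 6 stayed past the threshold after quantile normalization. These lists were picked as low in the same values, and the proteasome list, which did not pass, also lay below its range. The matched range therefore bears on brightness and not on chance. The oxidative phosphorylation median went from -0.50 to -0.41 (SD over rats 0.462 and 0.485), and with the smaller shift its adjusted p reached 0.0923 (0.000413 to 0.563 over its alternatives), so for this list scaling cannot be told apart. A smaller share of ganglion cells among the captured cells may contribute. The test assumed that it would raise markers of other cell types alike. The amacrine median lay -1.46 ± 1.39 (SD, n = 3 rats) from the mean of bipolar, photoreceptor, glial and microglial medians, with rat 2 at 0.13. That mean was 0.22, 0.20 and 0.36 in rats 1 to 3, while pigment epithelium and lens markers had medians of -1.72, -0.35 and -0.34. Whether other types should move alike is not known, so a smaller share stays open. Shorter amplified RNA in OS could also contribute, as 5 of 6 values of the 3' to 5' difference of the Gapdh and beta-actin controls were higher in OS, and 7 of 9 with hexokinase, but hexokinase was at -4.50 in rat 1 and Gapdh at -2.58 in rat 3. Of the 12 hexokinase values, 1 exceeded the background limit. The effect of raised pressure stays open as well, since the treated eye of each rat is not known.

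The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For lists, the split by eye gave 6 and the highest of the other splits 6, with 3 splits giving as many. The other splits with 6 part only the eyes of rat 1 and are the same fit once rat is a block, so they count 1 contrast more than once. Among the 4 splits that part every rat the highest other gave 3. For probe sets, the split by eye gave 2 and the highest other 0, so 1 split gave as many.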
